A study of Caenorhabditis elegans with 2 samples.

How the data were processed

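Total RNA of whole worms was hybridised, as biotin-labelled cRNA made from 6 ug of RNA, to Affymetrix arrays for Caenorhabditis elegans, per the labels' protocols. The comparison held 2 arrays, 1 of control worms and 1 of worms exposed to a-SWCNT, grouped by the treatment label. Values were deposited as 1 signal intensity per probe set on a linear scale, and MAS5 is the software named for them, per the submitters' processing notes. The MAS5 version, its scaling target and its detection calls were not given in the sources used here. Each array had 22625 probe sets, of which 77 were control probe sets of the manufacturer and 22548 measured worm transcripts.

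The signals had not been brought to a common level between the arrays. The mean after removal of 2% of the values at each end was 211 on the control array and 84.3 on the a-SWCNT array, a 2.50-fold difference, or -1.32 in log2. The design fixed before the data were examined had taken the signals as already scaled and would have compared them as deposited. Because of this difference, the results given are those after scaling the a-SWCNT array to the trimmed mean of the control array, which was among the alternatives fixed beforehand, and the values as deposited are given as an alternative. Scaling by 1 factor sets the average difference to about 0, so that a change shared by most transcripts cannot be seen in the scaled values.

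Signals below a floor of 56.7, the median of all worm signals pooled over both arrays after scaling, were raised to it before the log2 ratio of a-SWCNT over control was taken. A probe set was called measured on an array where its signal was at or above the floor, and 11377 probe sets (50.5%) were measured on the control array and 11171 (49.5%) on the a-SWCNT array. Where only 1 side was measured, the ratio to the floor is a bound and is written as at least N-fold. Probe sets were counted as higher or lower at a ratio of at least 2-fold. No p-value was computed, because there was 1 array per group.

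Gene names came from the platform's annotation, brought up to date by gene identifier through a reference gene table of the WBcel235 assembly. Of the probe sets, 20766 had 1 gene, 887 had several and were not named, and 895 worm probe sets were not listed in the annotation and stayed unnamed. Of those with 1 gene, 20701 were found in the reference table by identifier and 65 were not, and 0 symbols differed between the sources. They covered 17138 genes. The value of a gene was the mean log2 ratio of those of its probe sets that were measured on at least 1 array, and 9382 genes had such a value. No genome build belongs to the array annotation, so no coordinates are given, and the reference table served only for names, genomic spans, membership of the mitochondrial genome and the order of genes.

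Gene lists of pathways, stress responses, tissues and gene families were fixed before the data were examined, 44 in all. The 8 primary lists covered the tricarboxylic acid cycle, oxidative phosphorylation, endocytosis, genes raised by DAF-16, major sperm proteins, oocyte and germline genes, vitellogenins and collagens (genes named col). In the lists, 23 names had no match in the reference table, among them those given for genes of the mitochondrial DNA, which are therefore reported as a set grouped after the values were seen. For each list the median log2 ratio of its measured genes is given with an order-statistic 95% interval over genes (below 6 genes, their range), which describes spread between genes and not between animals. The percentile of the median among 10000 random lists of the same size, matched on mean signal in 20 bins, describes these arrays and is no test of the exposure. A list was called outside the random range where its median lay outside the central 95% of the random lists.

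Genes were named in the text by a rule fixed beforehand. It took the 12 highest and 12 lowest ratios among probe sets of 1 gene measured on both arrays, the 4 highest and 4 lowest bounds, up to 2 highest and 2 lowest members measured on both arrays of each list described, and 22 genes fixed by name. Genes named outside it are said to have been picked after their values were seen. Members of a list given as its highest or lowest are so among those measured on both arrays, and other members may lie beyond or between them.

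Alternatives fixed beforehand were scaling to the same median or 75th percentile, quantile normalisation, loess centring of the ratio against signal (span 0.3), floors at the 25th and 75th percentile or none, thresholds of 1.5-fold and 3-fold, both sides measured, removal of probe sets whose identifier has a letter suffix and which may bind several transcripts, the brightest probe set of a gene, and random lists without matching. Scaling to the hybridisation controls, random lists also matched on genomic span (10 signal bins and 5 span bins), and inclusion of probe sets shared by several genes of a list were added after the data were examined.

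The procedure was tested on simulated arrays of 22548 probe sets. Of 100 planted 4-fold differences 98% were recovered, and of 100 planted 3-fold differences 95% were. Of 22298 unchanged probe sets, 39 (0.175%) were called. The simulated noise had an SD of 0.34 in log2, that of the hybridisation controls, and differences were planted only in bright probe sets. In the data, ratios of probe sets measured on both arrays had an SD of 0.52, which includes any real differences. These rates therefore do not give the error of the counts of higher and lower probe sets. A list of 40 genes shifted by 0.5 in log2 was placed at percentile 100 and an unshifted list at percentile 75.8. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.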

Results

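Whole worms of the Caenorhabditis elegans wild-type strain N2 were profiled on 2 oligonucleotide arrays. The control array held RNA of worms raised without nanotubes. The other held RNA of worms raised with 500 μg/mL of a-SWCNT, a preparation of single-walled carbon nanotubes, which are hollow cylinders with a wall of 1 layer of carbon atoms. Exposure began in synchronised L1 larvae and lasted 48 hr at 22 °C, and both samples carried the age label L4, the last larval stage. There was 1 array per group, so no value has a replicate, a p-value or an error between cultures, and the number of arrays limits the precision. As a guide to error within the arrays, 1370 genes with 2 measured probe sets had log2 ratios that differed by a median of 0.43 between the probe sets, with a 95th percentile of 1.38.

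The comparison addressed which transcripts of the worm differed in abundance after growth with a-SWCNT. Transcripts of collagens named col, oocyte and germline genes, yolk proteins, pharyngeal genes and genes raised by the transcription factor DAF-16 were lower on the a-SWCNT array, with list medians between -0.62 and -0.33 in log2. The 10 genes commonly used as references for expression, at a median of -0.36, were as low as some of these lists. The medians of glutathione S-transferases (0.33), of the insulin signalling list (0.26) and of neuropeptide precursors (0.25) were above 0. With arrays scaled to the hybridisation controls, however, these medians were 0.14, 0.01 and -0.04. The insulin signalling list, with 15 of 23 genes above 0, shares members with the insulin-like peptide family (ins), in which 13 of 14 were. Its median therefore does not show a rise in the other genes of the pathway, which were not counted apart. Transcripts of the mitochondrial DNA were lower (median -1.05), while the preset lists of nuclear genes of oxidative phosphorylation and of the tricarboxylic acid cycle lay within the range of random gene lists.

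After scaling, 164 probe sets were at least 2-fold higher on the a-SWCNT array and 533 were at least 2-fold lower, so that 76.5% of these lay on the lower side. Of the 9382 genes measured, 133 were at least 2-fold higher and 270 at least 2-fold lower. This split depended on the scaling. It was 227 higher and 430 lower (65.4% lower) with equal medians, 276 and 360 (56.6%) with equal 75th percentiles, 217 and 415 (65.7%) after quantile normalisation, and 62 and 1162 (94.9%) with equal hybridisation controls. In the values as deposited it was 4 and 8375. The median log2 ratio of all probe sets was 0.01 with the scaling used, 0.14 with equal 75th percentiles, -0.26 with equal hybridisation controls and -1.31 as deposited, and all ratios are relative to that level.

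The highest ratio among probe sets measured on both arrays belonged to dct-7, a gene placed downstream of DAF-16, with a signal of 87.7 in control and 549 in a-SWCNT worms, 6.26-fold higher. Next came hrg-7, which encodes a secreted protein of haem homeostasis, with 862 in control and 4164 in a-SWCNT worms (4.83-fold). F59C12.4 (4.54-fold), F15E6.4 (4.46-fold), the C-type lectin gene clec-3 (4.15-fold), the cathepsin A homologue ctsa-4.1 (4.03-fold) and ZK218.5 (3.93-fold) followed. Also among the 12 highest were dod-17, a gene held down by DAF-16 (161 and 602, 3.73-fold), ndua-2, a subunit of mitochondrial complex I (474 and 1741, 3.67-fold), and the cuticle collagen gene dpy-17 (71.6 and 259, 3.61-fold). F42A10.7 (3.53-fold) and F15E6.3 (3.49-fold, with a log2 ratio of 1.06 in its other probe set) completed them. Probe sets below the floor in control worms were at least 4.80-fold higher for clec-233, 4.07-fold for ZK218.1, 3.23-fold for the cuticle collagen gene dpy-14 and 3.20-fold for the caveolin gene cav-1, whose mean log2 ratio over its 2 probe sets was lower, at 1.44.

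The lowest ratio belonged to T22F3.11, with 864 in control and 72.7 in a-SWCNT worms, 11.9-fold lower, and a log2 ratio of -2.50 in its other probe set. The log2 ratio of H39E23.3 was -3.33, while F23F1.2 was 7.87-fold, Y57E12B.4 6.56-fold and Y51H7C.13 5.28-fold lower. A trio of genes for SCP-like secreted proteins was among the lowest, with scl-13 at 6.06-fold, scl-11 at 5.96-fold and scl-12 at 5.62-fold lower. The scl family went both ways, with 5 of 10 measured genes above and 5 below 0. At least 2-fold higher, and picked after their values were seen, were scl-14 (88.0 and 202) and scl-24 (at least 2.35-fold). The bright C-type lectin gene clec-174 had 7398 in control and 1334 in a-SWCNT worms (5.54-fold lower). Among collagens, the adult cuticle gene bli-1 was 4.93-fold lower with -2.19 in its other probe set, emb-9, a type IV collagen of basement membranes, was 4.64-fold lower in 1 probe set and at -0.23 in the other, and col-97 was 4.58-fold lower in 1 and at -0.69 in the other. Probe sets below the floor in a-SWCNT worms were at least 4.95-fold lower for melo-1, 4.75-fold for tra-1, 4.69-fold for the aspartyl protease gene asp-9 and 4.42-fold for the cytochrome P450 gene cyp-35B2. The other probe sets of tra-1, a regulator of sexual fate, had log2 ratios of 0.37, 0.44 and 0.00, and those of melo-1 had -0.95, -0.87 and -1.23, so for both genes the value rests on which probe set is read. The probe sets named for F15E6.4, cav-1, H39E23.3, Y57E12B.4, scl-13 and clec-174 are of types that may bind several similar transcripts.

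**Figure D1:**
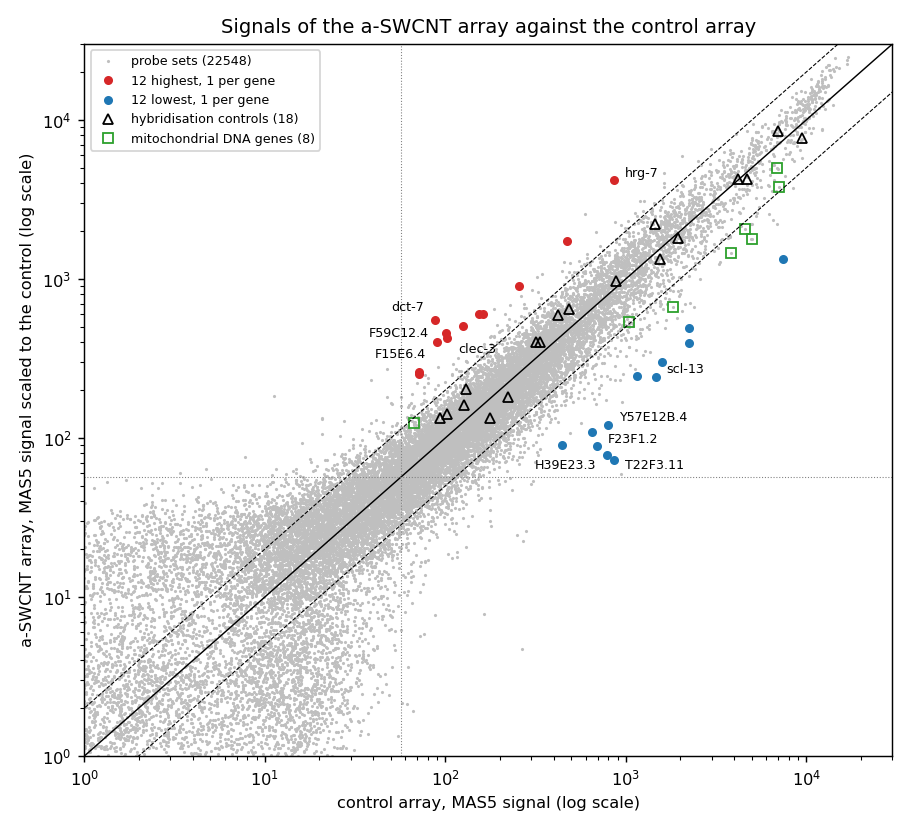
Signal of each of 22548 probe sets on the control array (x axis, log scale) and on the a-SWCNT array after scaling (y axis, log scale), with the line of equality, dashed lines at 2-fold and dotted lines at the floor of 56.7. The 12 highest and 12 lowest genes lie outside the dashed lines, from dct-7 at 6.26-fold higher to T22F3.11 at 11.9-fold lower, the 18 hybridisation control probe sets have a median log2 ratio of 0.27, and 7 of 8 mitochondrial DNA genes lie below the line of equality.

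Nuclear genes on the preset lists of energy metabolism differed little between the arrays. None of the 45 measured nuclear genes on the oxidative phosphorylation list was 2-fold different (0 higher, 0 lower), and their median of 0.14 lay at percentile 34.5 of the random lists and changed sign under loess centring and with equal hybridisation controls. The extremes were ucr-2.3 (-0.43) and nuo-4 (-0.37, the mean of probe sets at -0.99 and 0.26) on the lower side and lpd-5 (0.68) and sdha-1 (0.71) on the higher side. The genes fixed by name gave 0.19 and 0.27 for the probe sets of isp-1, 0.40 and 0.27 for gas-1, -0.19 for mev-1 and 0.01 for atp-2, of which atp-2 and the lower value of isp-1 changed sign between scalings. The tricarboxylic acid cycle list also had 0 of 29 genes at 2-fold, with a median of -0.05 at percentile 8.22 whose sign depended on the scaling. Its lowest were mdh-2 (-0.74, from -1.19 and -0.29) and idha-1 (-0.71, from -1.33 and -0.09) and its highest sdha-1 and aco-1 (0.73), with -0.40 for the citrate synthase gene cts-1, -0.08 for aco-2 and -0.11, -0.13 and -0.29 for the probe sets of icl-1; aco-2 and the first value of icl-1 changed sign between scalings. The 3.67-fold higher ndua-2 was not on the oxidative phosphorylation list, and neither were the complex I genes named ndub. Looked at after the values were seen, these were above 0 in 6 of 8 cases with ndub-8 at least 2-fold higher (1.28), at a median of 0.34 within the random range (percentile 82.5). The cox family was above 0 in 10 of 12 cases at a median of 0.29, also within the random range (percentile 91.7).

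Transcripts encoded by the mitochondrial DNA went the other way from ndua-2. In this set, grouped after the values were seen, 7 of 8 measured genes were lower on the a-SWCNT array and 4 of them at least 2-fold, with a median of -1.05, or 2.07-fold, below all 10000 random lists (percentile 0). The cytochrome oxidase genes COX1 (-1.50), COX2 (-1.45) and COX3 (-0.89), the complex I genes ND1 (-1.41) and ND4 (-0.47), the cytochrome b gene CYTB (-1.14) and the ATP synthase gene ATP6 (-0.96) were lower, and ND5, a dim probe set with 67.5 in control and 124 in a-SWCNT worms, stood at 0.88. The median stayed between -1.32 and -0.92 in all scalings other than as deposited. The 5 probe sets of the ribosomal RNA gene rrn-3.1 were also lower, at a median of -1.15.

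Genes known to be raised by DAF-16, the FOXO factor of the insulin pathway, had a median of -0.33 over 20 measured genes (interval over genes -0.89 to 0.23) at percentile 0.09. On this list 0 genes were at least 2-fold higher and 4 at least 2-fold lower: cyp-35B1 (-2.19), the small heat shock protein genes hsp-12.6 (-1.56) and hsp-16.41 (-1.34), and the manganese superoxide dismutase gene sod-3 (-1.13, from 317 to 145). The metallothionein gene mtl-1 had -0.74, hsp-16.2 -0.34, the lysozyme gene lys-8 0.50 and gst-4 0.68. Genes known to be held down by DAF-16 had a median of 0.40 over 9 measured genes (percentile 99.0, interval -0.62 to 1.04), led by dod-17 (1.90) and dod-23 (1.04), with the yolk genes vit-5 (-0.62) and vit-2 (-1.63) at its low end. With equal 75th percentiles this list lay within the random range. The probe sets of daf-16 itself gave -0.41, 0.14 and -0.00, the last 2 with signs that depended on the scaling, and a further probe set was below the floor on both arrays. The insulin-like gene ins-7 gave 0.54.

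Stress genes did not move as a block. The heat shock list had 3 of 16 genes at least 2-fold lower and 0 higher, at a median of -0.21 and percentile 2.15, on the edge of the random range, with hsp-12.6 and hsp-16.41 lowest and hsp-90 (0.22) and hsp-17 (0.69) highest; the value of hsp-90 changed sign with equal hybridisation controls. The endoplasmic reticulum chaperone gene hsp-4 had -0.10, and the mitochondrial chaperone gene hsp-6 had 0.10 and 0.93 in its probe sets; the value of hsp-4 and the lower value of hsp-6 changed sign between scalings. On the list of the mitochondrial unfolded protein response, within the random range at percentile 74.8, the import gene timm-23 (1.06) was highest. The metallothionein gene mtl-2 had 0.70, 0.86 and 0.37 in its 3 probe sets. Glutathione S-transferases, which conjugate foreign compounds, had a median of 0.33 over 33 genes (percentile 99.96, interval -0.02 to 0.61), with 22 above and 11 below 0. Among those measured on both arrays, gst-38 (1.38) and gsto-1 (0.97) were highest and gst-3 (-0.87) and gst-41 (-0.66) lowest. Outside that group, gst-19, picked after its value was seen, lay below gst-3. Cytochrome P450 genes had 5 of 37 genes at least 2-fold lower and 0 higher, at a median of -0.25 and percentile 2.14. They were cyp-35B1, cyp-35B2 and cyp-35A2 (-1.38) and, picked after their values were seen, cyp-35C1 (-1.33, a bound) and cyp-33A1 (-1.24). Among P450 genes measured on both arrays, cyp-33C8 (0.41) and cyp-13A2 (0.93) were highest. Over all measured P450 genes, cyp-34A2 and cyp-13A10, also picked after their values were seen, lay above cyp-33C8. The P450 percentile passed into the random range in 4 of the 7 scalings, at most 5.97, and when random lists were also matched on genomic span (4.01). Transporters of the P-glycoprotein and MRP families had a median of 0.39 over 13 genes at percentile 99.75, or 90.4 as deposited, from mrp-4 (-0.95) to mrp-2 (0.67).

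Collagens named col, most of them structural proteins of the cuticle, were lower as a family. Of 103 measured col genes 68 were below and 35 above 0, 12 were at least 2-fold lower and 2 at least 2-fold higher, and the median of -0.34 (interval -0.45 to -0.12) lay at percentile 0. Collagen genes under other names, such as bli-1, emb-9, dpy-17 and dpy-14, were not on this list. The dpy family, only part of which encodes collagens, did not share its direction, with 2 of 22 genes at least 2-fold higher, 0 lower and a median of 0.04 whose sign depended on the scaling. The lowest col genes were col-183 (-1.69) and col-51 (-1.67), the highest col-165 (1.67) and col-118 (1.02), and col-19, a marker of the adult cuticle, had -0.84. All 3 measured adult cuticle genes were below 0, with bli-1 at -2.25, col-19 and bli-2 at -0.17 (percentile 0.55). Genes of the moult had 7 of 53 at least 2-fold lower and 0 higher at a median of -0.21 (percentile 0.24), with grd-7 (-1.43) and the period homologue lin-42 (-1.31) lowest and nhr-23 (0.93) and grd-10 (0.69) highest.

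Oocyte and germline genes were lower in 40 of 50 cases, 7 of them at least 2-fold and 0 at least 2-fold higher, at a median of -0.41 (interval -0.57 to -0.18) and percentile 0. The RNA-binding regulator gld-1 (-1.38) and the eggshell gene cpg-1 (-1.26) were lowest, cpg-3 (0.42) and puf-5 (0.27) highest, and the yolk receptor gene rme-2 had 0.10, which changed sign between scalings. Vitellogenins, the yolk proteins made in the adult intestine, were below 0 in 4 of 5 genes at a median of -0.62 (range -1.63 to 0.02) and percentile 0.42. With equal hybridisation controls the gene above 0 was no longer measured. The median of the 4 left was -1.31, midway between vit-6 (-1.71) and vit-5 (-0.90) in that scaling. The signal of vit-2 was 359 in control and 116 in a-SWCNT worms (-1.63), and vit-6 (-1.44), vit-5 (-0.62) and vit-4 (-0.36) followed. Major sperm proteins, which drive sperm crawling, had 0 of 23 genes at 2-fold and a median of 0.10 (interval -0.01 to 0.31) at percentile 13.0, or 3.04 among random lists also matched on genomic span, from msp-74 (-0.43) and msp-36 (-0.15) to msp-49 (0.43) and msp-31 (0.44). The sign of this median changed under loess centring and with equal hybridisation controls.

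**Figure D2:**
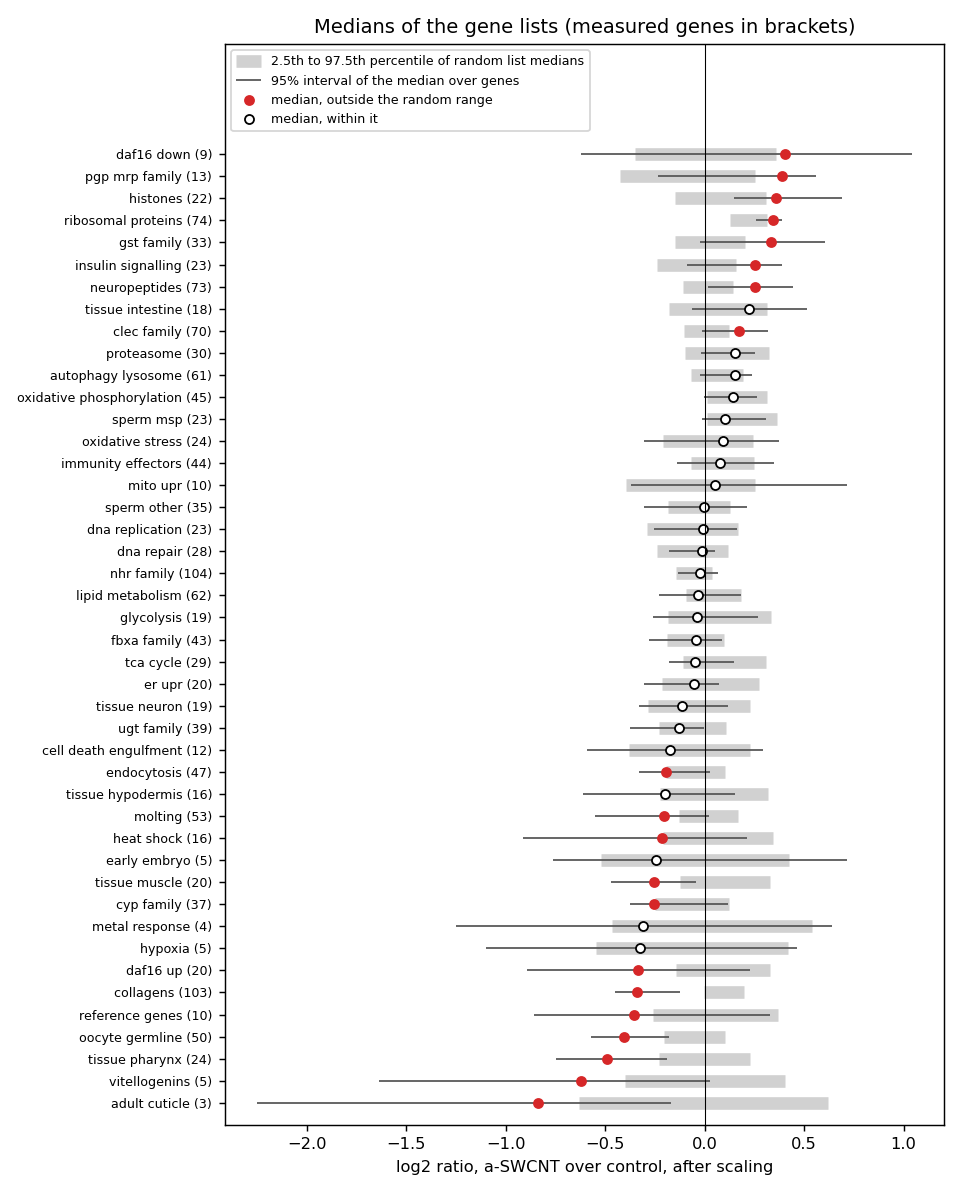
Median log2 ratio of a-SWCNT over control (x axis) of each of 44 gene lists, with the 95% interval over genes (line) and the central 95% of random list medians (grey bar). Medians run from -0.84 for 3 adult cuticle genes to 0.40 for genes held down by DAF-16; 12 lists lie below and 8 above the random range, and among those above it the neuropeptide and C-type lectin medians fell below 0 with equal hybridisation controls.

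Tissue lists differed from one another. Pharyngeal genes had 3 of 24 at least 2-fold lower and 0 higher at a median of -0.49 (interval -0.75 to -0.19) and percentile 0, with the pharyngeal myosin gene myo-2 (-1.30) and abu-10 (-1.13) lowest and phat-5 (0.62) and phat-6 (0.53) highest. Body wall muscle genes were below 0 in 16 of 20 cases at a median of -0.25 (interval -0.47 to -0.04) and percentile 0.28, led by the myosin heavy chain gene unc-54 (-1.03) and tni-3 (-0.82), with tni-1 (0.36) and mup-2 (0.22, reversed in sign with equal hybridisation controls) highest. Neuronal genes had a median of -0.11 at percentile 22.9, intestinal genes 0.22 at percentile 88.4 and hypodermal genes -0.20 at percentile 3.38, all within the random range with the scaling used, and the first and second of these medians changed sign between scalings. The hypodermal list lay below the random range in 3 of the 7 scalings (1.60 under loess centring) and when random lists were also matched on genomic span (2.27). The intestinal list lay above it under loess centring (98.17). Their extremes were unc-64 (-0.89) and mec-12 (0.84) in neurons, nhx-2 (-0.43) and vha-6 (1.11) in the intestine, and che-14 (-0.91) and dpy-17 (1.85) in the hypodermis. The 10 genes commonly used as references for expression were not level, with a median of -0.36 (percentile 0.65, or 3.66 with equal hybridisation controls) from the actin gene act-3 (-1.05) and ama-1 (-0.86) to the tubulin genes tbb-1 (0.33) and tba-1 (0.46). No probe set was specific to act-1.

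Neuropeptide precursors had 5 of 73 genes at least 2-fold higher and 0 lower, at a median of 0.25 (interval 0.02 to 0.44) and percentile 99.98, with flp-24 (1.35) and flp-4 (1.30) highest and nlp-16 (-0.70) and nlp-101 (-0.65) lowest; with equal hybridisation controls the median was -0.04. Insulin signalling genes had a median of 0.26 over 23 genes (interval -0.09 to 0.39) at percentile 99.84, from akt-1 (-0.78) and age-1 (-0.32) to the insulin-like genes ins-18 (0.79) and ins-11 (1.57), and this percentile was 95.2 as deposited. Of the 23 genes, 15 were above 0, against 13 of 14 in the insulin-like peptide family (ins), with which the list shares members. The list median therefore does not show a rise in its members other than insulin-like peptides, which were not counted apart. C-type lectin genes, many of them linked to defence, went both ways, with 6 of 70 at least 2-fold higher and 6 at least 2-fold lower, and their median of 0.17 (percentile 99.8) turned to -0.03 with equal hybridisation controls. Here clec-3 (2.05) and clec-45 (1.64) stood against clec-174 (-2.47) and clec-61 (-1.87). Ribosomal protein genes (median 0.34, 67 of 74 above 0) and histone genes (median 0.36, 19 of 22 above 0) lay at percentiles 99.7 and 99.28. They lay at 90.6 and 89.9 among random lists also matched on genomic span, and the ribosomal list lay at 17.8 after quantile normalisation. Relative to random lists matched on signal and span, the ribosomal median was 0.065 (interval -0.017 to 0.113). Random lists of equal signal had mean medians of 0.21 for the ribosomal and 0.08 for the histone list, so counts above 0 overstate the difference for these lists. Both are lists of mostly short genes, and the shortest 937 genes had a median of 0.23 against -0.10 for the longest 937. The ratio of signal at the end of a transcript to that at its start, a sign of RNA quality, was 14.3 in control and 23.1 in a-SWCNT worms for ubiquitin, and lower in a-SWCNT worms for actin (1.13 and 0.899), GAPDH (0.779 and 0.687) and catalase (2.41 and 1.96). Members of these lists ran from rps-20 (-0.41, from -1.29 and 0.48) to rpl-14 (0.76) and from his-32 (-0.36) to his-3 (1.09).

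Endocytosis genes had 1 of 47 at least 2-fold higher, cav-1, and 1 at least 2-fold lower, the GTPase gene rab-11.2 (-1.28). The median of -0.19 (interval -0.33 to 0.03) lay at percentile 2.43, just outside the random range, and within it in all other scalings (at most 8.66) and when random lists were also matched on genomic span (3.24). Its other extremes were amph-1 (-0.87, from -1.55 and -0.19), vps-45 (0.84) and aps-2 (0.61). Lipid metabolism genes had a median of -0.03 at percentile 12.7, which changed sign between scalings, with acs-2 (-1.40) and acs-11 (-0.90) lowest and the carnitine palmitoyltransferase gene cpt-1 (1.21) and maoc-1 (2.14-fold higher) highest. Immunity effector genes had 6 of 44 at least 2-fold higher and 2 at least 2-fold lower, at a median of 0.08 and percentile 37.8 with a sign that depended on the scaling. Among them spp-14 (2.84-fold) and F55G11.2 (2.58-fold) were highest and spp-27 (-1.61) and ilys-3 (-1.33) lowest.

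**Figure D3:**
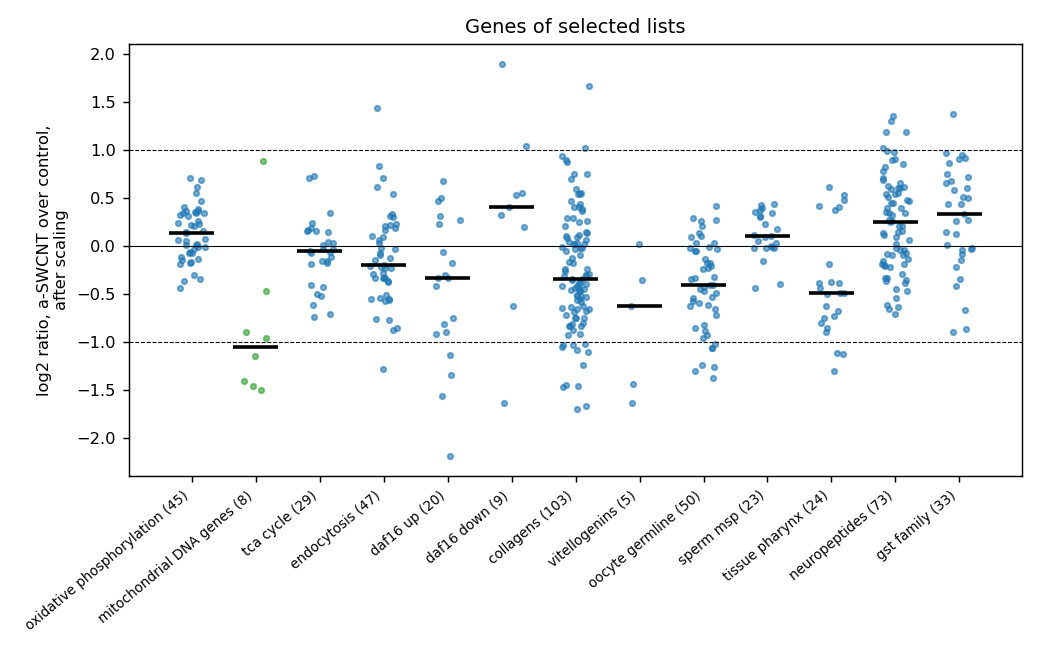
Log2 ratio of a-SWCNT over control (y axis) of each measured gene (points) in 12 lists and in the mitochondrial DNA set, with the median of each as a bar and dashed lines at 2-fold. Collagens (median -0.34), oocyte and germline genes (-0.41) and the 8 mitochondrial DNA genes (-1.05) sit mostly below 0, and the medians of oxidative phosphorylation (0.14), the tricarboxylic acid cycle (-0.05), major sperm proteins (0.10) and neuropeptides (0.25) lie near it and changed sign in at least 1 other scaling.

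Of the 44 lists, 12 lay below and 8 above the random range and 24 within it, where 2.2 would lie outside if genes and lists varied independently. Lists share genes, and genes of a list may vary together between any 2 preparations, so this comparison is no test. Of the 20 outside, 12 stayed on their side in all 7 scalings and 16 when random lists were also matched on genomic span. Apart from quantile normalisation and loess centring, the scalings differ only by a factor between the arrays, which moves a list and its random lists alike. Among them a percentile can change mainly through the floor, so staying on the same side was largely fixed in advance. In the values as deposited the median of every list was below 0.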

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

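Scaling to the hybridisation controls, matching on genomic span and inclusion of probe sets shared by genes of a list were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because each group had 1 array, and no replicate existed to leave out. The log2 ratios of the 63 probe sets of named genes and of 168 named list members kept within 0.34, the SD of the hybridisation controls, in every scaling other than as deposited. For scalings by 1 factor this was fixed by the size of the factor, which was 0.27 in log2 for the hybridisation controls relative to the scaling used. Some small ratios still changed sign. Below the floor on both arrays were 10528 probe sets, whose ratios were not read. As the floor is the median of all worm signals, this number does not measure signal over background.

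As deposited, with no factor between the arrays, 4 probe sets were at least 2-fold higher and 8375 lower. The list medians were then -1.36 for the tricarboxylic acid cycle, -1.18 for oxidative phosphorylation, -1.41 for endocytosis, -1.66 for genes raised by DAF-16, -1.22 for major sperm proteins, -1.95 for vitellogenins, -1.63 for collagens and -1.55 for oocyte genes. Every list median was then below 0, so each one above 0 after scaling changed sign. Among lists whose interval had lain wholly above 0 these were neuropeptides (-1.02), ribosomal proteins (-0.97) and histones (-0.96). Of named list members at least 2-fold higher after scaling, those that changed sign were dod-23 (-0.28), col-118 (-0.31), flp-4 (-0.022), vha-6 (-0.22), timm-23 (-0.26), maoc-1 (-0.23), cpt-1 (-0.11), his-64 (-0.27), his-3 (-0.24) and asp-12 (-0.18), and members with smaller ratios, nhr-23 among them, did so too. Scaled to the hybridisation controls, 62 were higher and 1162 lower, and medians were -0.32 for the tricarboxylic acid cycle, -0.13 for oxidative phosphorylation, -0.42 for endocytosis, -0.17 for major sperm proteins, -1.31 for vitellogenins, -0.59 for collagens, -0.65 for oocyte genes and, reversed, -0.038 for neuropeptides. Both follow mostly from the factor applied to every probe set. The floor, taken again after each scaling, also changed which genes were measured and which ratios were bounds. The vitellogenin median of -1.31 lies midway between vit-6 (-1.71) and vit-5 (-0.90), because the gene above 0 was then no longer measured. Equal 75th percentiles gave 276 higher and a median of 0.27 for oxidative phosphorylation, again by the factor between the arrays. Loess centring gave -0.0075 for oxidative phosphorylation and -0.024 for major sperm proteins. With the scaling used, random lists of equal signal had mean medians of 0.16 and 0.20 for these lists. Loess centring removes such a dependence of the ratio on signal by construction, and no other cause was tested.

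Counts of higher and lower probe sets were 741 and 1015 with the floor at the 25th percentile, 89 and 204 at the 75th, and 2844 and 2785 without a floor, where dim probe sets enter by construction. They were 988 and 1714 at 1.5-fold and 24 and 91 at 3-fold. Without probe sets with a letter suffix, 98 were higher, by construction from fewer probe sets, and the vitellogenin median was -1.635, the value of vit-2 as the middle of 3 genes left.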

Other observations

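The scans of gene families and of neighbouring genes were chosen after the data were seen, as were the tests of poly(A) tails, ribosomal RNA, exposure, germline RNA, developmental stage, the amount of worm RNA and whole-array brightness. Matching on genomic span was added after the data were seen but before its own result was known, and the test of bright probe sets was likewise set before its result.

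Among 132 gene families with at least 8 measured members, 8 had medians below and 10 above the central 95% of signal-matched random lists. If genes varied independently, 3.3 would lie in each tail, but members of a family may vary together. On the lower side, all 9 measured abu genes, which encode glutamine- and asparagine-rich proteins of the pharynx, were below 0 with a median of -0.75. The hedgehog-related grl family had a median of -0.58 over 18 genes, with grl-9 (-1.15) and grl-20 (-1.01) both at least 2-fold lower, and the bestrophin chloride channel family best had -0.48 over 15 genes. On the higher side, 21 of 23 genes for proteins of the small subunit of the mitochondrial ribosome (mrps) were above 0 with a median of 0.37, opposite in direction to the transcripts of the mitochondrial DNA. The large-subunit family (mrpl) was above 0 in 25 of 33 cases with a median of 0.26, which turned to -0.02 with equal hybridisation controls. Insulin-like peptide genes (ins) were above 0 in 13 of 14 cases with a median of 0.36, and nssp genes in 30 of 36 cases with a median of 0.43. Apart from mrpl, none of these medians changed sign in the scalings other than as deposited. The abu and ins families share members with the pharyngeal and insulin signalling lists.

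Genes that differed also lay beside one another. Among protein-coding genes at least 2-fold higher, 7 pairs were next to each other in the order of measured genes, against a mean of 1.84 in 10000 random draws, of which the highest had 8. They came from 3 places: dct-7, F15E6.4 and F15E6.3 (log2 ratios 2.65, 2.16 and 1.43), ZK218.1, ZK218.5 and ZK218.7 (at least 2.03, 1.97 and at least 1.53), and Y39G8B.7, F01D5.1, F01D5.2 and F01D5.3 (1.52, 1.22, 1.37 and 1.58). Among genes at least 2-fold lower there were 20 pairs, against a mean of 7.47 and a highest count of 19, with col-50 and col-51, scl-12 and scl-13, and cyp-35B1 and cyp-35B2 among them. Whether similar sequences of such neighbours share signal on the array was not tested.

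Transcripts of the mitochondrial DNA were lower on the a-SWCNT array. A shift of bright probe sets as a class is argued against by the set's percentile of 0 among lists of equal signal. A lower yield of RNA without long poly(A) tails is not decided. The histone list had a median of 0.36 (interval 0.15 to 0.69), far from the -1.05 to be explained. Relative to random lists of equal signal and genomic span it was 0.14 (-0.07 to 0.47). Ribosomal RNA also lacks such tails, however, and the lower rrn-3.1 probe sets go with this explanation. A priming or labelling effect shared with ribosomal RNA may account for the pattern, since the rrn-3.1 probe sets had a median of -1.15, although a dim probe set of rrn-3.56, below the floor in control, stood at 0.65. An effect of the exposure, at a median of -1.05, stays open as well, because 1 array per group keeps it from being told apart from a difference between the preparations.

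Genes of the collagen (col), oocyte and yolk lists were lower, while the median of major sperm proteins was 0.10 and within the random range. Genomic span as the cause is argued against by percentiles of 0 for collagens, 0 for oocyte and germline genes and 0.54 for vitellogenins among random lists also matched on it. Genomic span includes introns, so an effect of the length of the transcript itself was not tested and stays open. A smaller share of all germline RNA would not lower somatic transcripts, which counts against it for collagens, at -0.48 (interval -0.59 to -0.27) relative to random lists of equal signal and span; it stays open for the oocyte list at -0.34 (-0.50 to -0.11), whose interval overlaps that of major sperm proteins at -0.18 (-0.29 to 0.03), and 5 vitellogenins at -0.55 (range -1.57 to 0.09) do not decide. Another candidate explanation is that the exposed worms were at an earlier stage when collected, since L4 worms make sperm before oocytes, yolk and adult cuticle. The adult cuticle list lay at percentile 0.55, but with 3 measured genes and stage not separable from exposure this cannot be told apart from an effect on these genes at the same stage.

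As deposited, signals were lower on the a-SWCNT array. Less worm RNA on that array as the whole cause is argued against by the hybridisation controls, 18 probe sets for 4 bacterial and phage transcripts added to each sample, whose median over transcripts was -1.12 as deposited. The range over the 4 transcripts, -1.40 to -0.92, holds the shift of -1.32, which is consistent with lower brightness of the whole array, although 4 values place it only roughly. After scaling, the control probe sets stood at a median of 0.27, so a smaller difference in worm RNA stays open.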
